A study of Homo sapiens with 9 samples.

How the data were processed

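Polyadenylated RNA of 9 MCF-7 libraries was sequenced in pairs of reads on an Illumina NovaSeq after a stranded library preparation, per the series labels. There were 3 groups of 3 libraries each, DMSO, ZN-c5 (1 µM) and 4-hydroxytamoxifen (4-OHT, 1 µM), all treated for 24 hours. Groups were taken from the labels, which give no batches and do not say whether replicates were separate cultures.

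The count values were deposited as whole numbers of reads per Ensembl gene and library, without scaling. The FPKM values were deposited beside them and, per the series design text, computed by the authors with StringTie from aggregated gene counts. Per the submitters' processing notes, the tools used upstream were cutadapt, FastQC, HISAT2, StringTie and edgeR with the GRCh38 genome, for which no versions and no roles are given. The gene annotation release, the way counts were aggregated and whether the strand was used in counting are not given in the sources used here. Genes without reads carry an FPKM of 0.0001 in the table. The table held 58825 genes, of which 26142 had no reads in any library and 58472 were matched by Ensembl ID to a table of gene names. Of the genes tested, 20272 were matched. Names shared by several genes (9959) were kept apart by ID.

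Counts were analysed with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0, the data.table package in version 1.17.8). Genes were kept with filterByExpr (20386 genes) and libraries scaled by TMM. All 9 libraries were fitted together with 1 mean per group (estimateDisp, glmQLFit with robust estimation, 6 residual degrees of freedom), and 3 differences were tested by edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Counts of genes that also changed at least 2-fold stand beside the counts of all calls. The common biological coefficient of variation was 0.379. The median standard error of a log2 fold change was 0.18 among genes with an average log2 CPM of at least 3. Intervals are 95% intervals. CPM are scaled by TMM.

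The 22 gene lists were written before the data were examined, as were the tests, the other settings of each test and the rule for naming genes. They covered estrogen-induced, estrogen-repressed and luminal identity genes, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and quiescence, p53 targets, cholesterol synthesis and uptake, fatty acid synthesis, cholesterol efflux (LXR targets), lysosome, unfolded protein and amino acid stress, aryl hydrocarbon receptor targets, NRF2 targets, interferon-stimulated genes, the BCL2 family, growth factor receptors, ribosome biogenesis with MYC-linked genes, hypoxia and glycolysis, basal and mesenchymal markers, markers of other cell types, and mitochondrially encoded mRNAs. Some genes belong to more than 1 list. Lists were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, adjusted over the 66 tests of lists and comparisons. An estimated correlation and limma's fry were alternatives. Members were also counted with the adjustment over the list alone.

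Genes were named by a fixed rule for each comparison. It took ESR1, PGR, GREB1, TFF1, CCND1, MYC and MKI67 in every case. It added the 5 highest and 5 lowest log2 fold changes among genes with a symbol, an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the libraries of the groups. From each list that passed, or had at least 1 in 3 of its tested members past the threshold, it took up to 4 members with the lowest adjusted p, and 1 from any other list. Genes outside this rule are said to have been named after their values were seen.

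Shared responses were counted as genes called with both compounds. Because both used the same 3 DMSO libraries, 20 simulations of unchanged groups against these controls gave values for comparison. A further 20 simulations, with ZN-c5 at its measured means and 4-OHT at the DMSO means, gave the share of genes with the same sign when 4-OHT has no effect. In 20 more, both compounds had the mean of their measured levels. The size of the responses was compared by the slope of a Deming line through the origin, with equal error variances. Genes called for the mean of both compounds against DMSO were a second choice of genes for that line, made after seeing the data.

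Other settings chosen before the data were examined were DESeq2 median-of-ratios, upper-quartile and library-total scaling, no low-count filter, a filter of 5 CPM in 3 libraries, the DESeq2 test, limma-trend, fits of the 6 libraries compared, a block for the replicate number, each library left out, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). Settings chosen after seeing the data were a term for the 3 libraries with over 20% of reads on the mitochondrial chromosome, the 6 other libraries alone, the fit without mitochondrial genes and the fit without genes counted at least 4-fold apart in 1 library of a group. KEGG pathways given in the deposited table (307) were tested with camera after the other results were seen. Genes that mark sex were left out of the reported results.

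The steps were tested on simulated data with the depth and dispersion of these libraries. Of 100 genes changed 2-fold and 100 changed 4-fold, edgeR called 12 and 54, with 2 calls among unchanged genes of that comparison and 0 in a comparison without changes, where DESeq2 called 29 and 76, with 60 and 19 such calls. Among genes with an average log2 CPM of at least 1, edgeR called 12 of 57 and 51 of 66. A list changed 1.5-fold was called (camera adjusted p = 4.82e-18), no other list was, and a slope set to 2 was recovered as 1.91. Genes were drawn on their own there, so the absence of other list calls does not carry over to genes that vary together. Other splits of the real libraries called up to 9, 5 and 5 lists in the 3 comparisons. Each such split sets 2 libraries of 1 group and 1 of the other against the rest. Part of a true difference is kept, so these calls need not all be false. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.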

Results

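RNA was sequenced from MCF-7 cells, an established human breast cancer line that expresses estrogen receptor alpha, grown for 48 hours without phenol red in medium whose 10% serum had been stripped of steroids with charcoal. The cells then received vehicle (DMSO), ZN-c5 at 1 µM or 4-hydroxytamoxifen (4-OHT) at 1 µM for 24 hours. ZN-c5 is an investigational oral degrader of the estrogen receptor, and 4-OHT is an active metabolite of tamoxifen that binds the same receptor. Each group held 3 libraries, 9 in all. Counted reads came to 73195081, 64965226 and 69171784 in DMSO 1 to 3, 70900596, 72238964 and 73177380 in ZN-c5 1 to 3, and 73033190, 67710477 and 73048419 in 4-OHT 1 to 3. Of the 58825 genes in the table, 20386 had enough reads to be tested. Among the 10169 of them with an average log2 CPM of at least 3, the median standard error of a log2 fold change was 0.18. Nothing in the labels says whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

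Within a group, pairs of libraries had Spearman correlations of 0.963 to 0.974 across genes. The share of reads on genes of the mitochondrial chromosome differed between libraries of one group: 31.0%, 12.2% and 23.4% in DMSO 1 to 3, 16.2%, 12.45% and 20.7% in ZN-c5 1 to 3, and 12.95%, 14.2% and 14.9% in 4-OHT 1 to 3. DMSO 1, DMSO 3 and ZN-c5 3 lay above 20%, and the same 3 libraries had the lowest shares of ribosomal-protein reads, 5.66%, 7.03% and 7.12% against 9.94% to 11.2% in the other 6. They stood apart on the first principal component, which held 19.8% of the variance. The 3 ZN-c5 libraries lay between -58.5 and -53.0 on the second component (17.4% of the variance). All 6 others lay at 12.8 or above. Values within each set of libraries are given below as differences of mean log2 CPM (prior count 2), which are not edgeR fold changes. They were taken between the 1 ZN-c5 and 2 DMSO libraries of high mitochondrial share, and between the 2 ZN-c5, 3 4-OHT and 1 DMSO libraries of low share. No 4-OHT library had a high share.

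**Figure D1:**
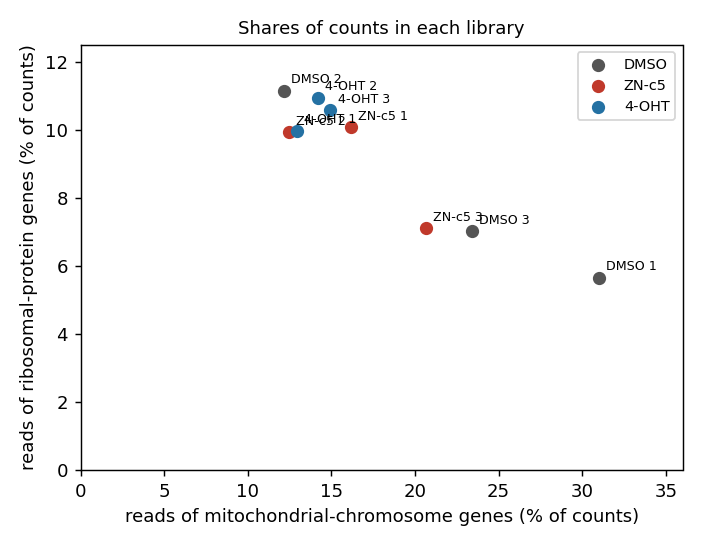
Share of counted reads on genes of the mitochondrial chromosome (x axis, %) and on ribosomal-protein genes (y axis, %) in each of the 9 libraries, with 1 point per library. DMSO 1 (31.0%), DMSO 3 (23.4%) and ZN-c5 3 (20.7%) lie to the right of the other 6 libraries.

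The first comparison asked which genes 24 hours of ZN-c5 changed against DMSO. Many genes that estrogen induces fell. PGR, which encodes the progesterone receptor (GRCh38 chromosome 11, 101029624 to 101130524), went from 28.3 ± 2.89 to 4.09 ± 0.30 CPM (counts scaled to library size; mean ± SD, n = 3 libraries each), a log2 fold change of -2.79 (SE 0.22, edgeR adjusted p = 0.000809). GREB1, a coregulator of the receptor (chromosome 2, 11482341 to 11642788), went from 208 ± 32.4 to 18.6 ± 3.16 CPM (log2 -3.48, SE 0.30, edgeR adjusted p = 0.000809). STC2, which encodes the secreted glycoprotein stanniocalcin 2 (chromosome 5, 173314713 to 173329503), went from 660 ± 4.26 to 57.8 ± 3.02 CPM (log2 -3.51, SE 0.15, edgeR adjusted p = 3.9e-05). Of the 50 genes in the list of estrogen-induced genes, 0 rose, 25 fell and 25 did not pass, and 40 fell when adjusted over the list alone. TPD52L1 (log2 -1.74, SE 0.11) and CXCL12, a chemokine (log2 -2.38, SE 0.17), were among them. The list as a whole fell (mean log2 -1.32, camera adjusted p = 2e-30), and its mean difference was -1.24 among the libraries of high mitochondrial share and -1.37 among those of low share. Of 20 estrogen-repressed genes 3 rose, 0 fell and 17 did not pass, against 9 up and 1 down when adjusted over the list alone. IL1R1, the interleukin 1 receptor, rose by log2 1.24 (SE 0.20), PSCA, a cell surface antigen, by 1.58 (SE 0.26), and EFNA1, an ephrin ligand, by 0.70 (SE 0.13). That list rose (mean log2 0.53, camera adjusted p = 2e-06), with differences of 0.62 and 0.53 in the libraries of high and low share.

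ESR1, the gene of estrogen receptor alpha itself (chromosome 6, 151656691 to 152103274), could not be compared. It was counted at 29.7, 254 and 197 CPM in DMSO 1 to 3, at 198, 38.6 and 227 CPM in ZN-c5 1 to 3 and at 204, 173 and 15.6 CPM in 4-OHT 1 to 3, so that 1 library of each group lay far below the other 2. The log2 fold change with ZN-c5 was -0.05 with a 95% interval of -2.45 to 2.35. TFF1, a secreted trefoil protein, fell by 0.96 on the log2 scale (SE 0.20, edgeR adjusted p = 0.0383), but passed in only 2 of the 9 fits that left out 1 library, with adjusted p up to 0.131. Cyclin D1 (CCND1) did not pass (log2 -0.61, SE 0.16, edgeR adjusted p = 0.0886).

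**Figure D2:**
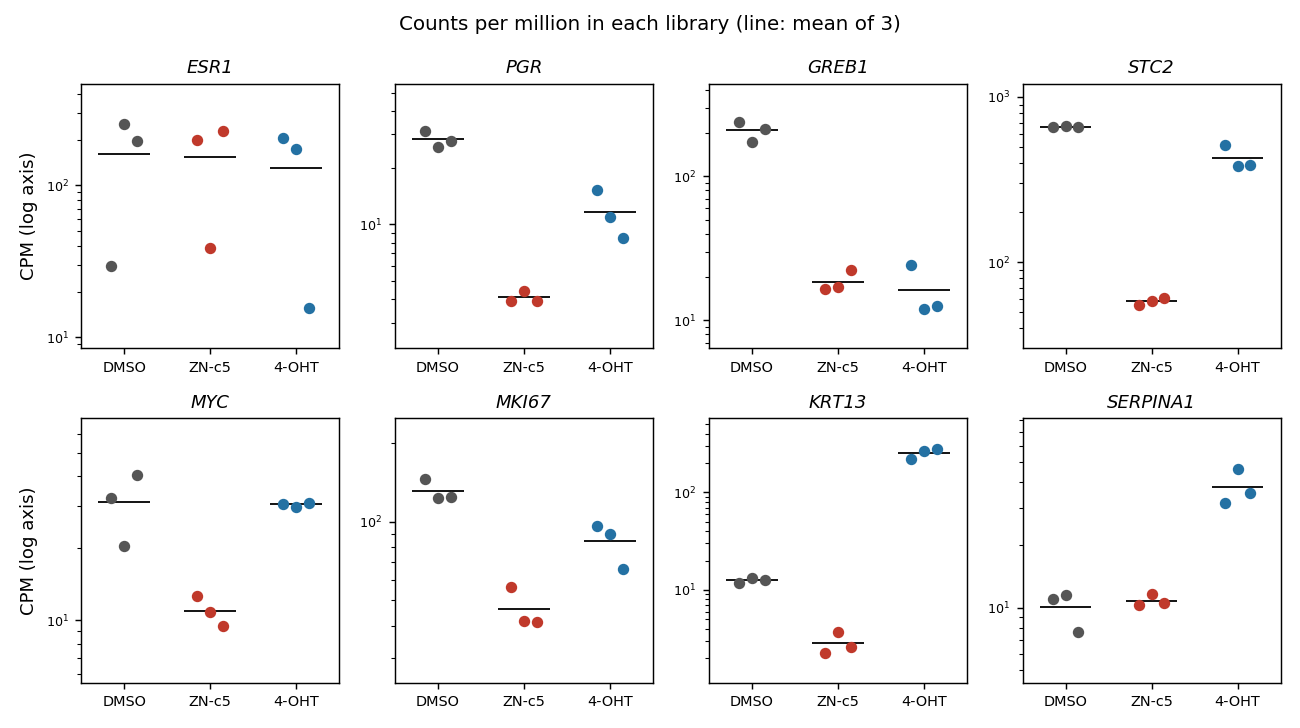
CPM (log axis) of 8 genes in each of the 9 libraries, by group (x axis), with the mean of the 3 libraries of a group as a line. PGR, GREB1, STC2, MYC and MKI67 lie lower in all ZN-c5 libraries than in all DMSO libraries, KRT13 spans 2.86 to 255 CPM between the ZN-c5 and 4-OHT means, and ESR1 has 1 low library in every group.

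Most genes of DNA replication and some genes of cell division fell with ZN-c5. Of 36 genes of the G1/S transition and DNA replication, 0 rose, 32 fell and 4 did not pass, and all 36 fell when adjusted over the list alone (mean log2 -1.43, camera adjusted p = 8.87e-43). Subunits of the MCM replicative helicase were among them, with MCM6 at log2 -1.35 (SE 0.10), MCM3 at -1.24 (SE 0.11) and MCM4 at -1.19 (SE 0.10), as was the transcription factor E2F1 at -1.95 (SE 0.15, edgeR adjusted p = 0.000764). The list differed by -1.50 and -1.44 in the libraries of high and low mitochondrial share. MKI67, which encodes the proliferation marker Ki-67, fell from 131 ± 12.9 to 46.4 ± 8.58 CPM (log2 -1.50, SE 0.18, edgeR adjusted p = 0.00352). Of 34 genes of G2/M and mitosis, 0 rose, 12 fell and 22 did not pass, with 24 down when adjusted over the list alone. The kinetochore gene NDC80 (log2 -1.0, SE 0.13), the kinase gene CDK1 (-0.86, SE 0.12) and the mitotic kinesin gene KIF11 (-0.92, SE 0.13) were examples. The G2/M list had a mean log2 of -0.65 (camera adjusted p = 5.99e-16; adjusted p = 0.0876 with an estimated correlation), and differed by -0.88 and -0.53 in the libraries of high and low share. MYC, a transcription factor that drives growth, fell from 31.2 ± 10.2 to 11 ± 1.6 CPM (log2 -1.51, SE 0.24, edgeR adjusted p = 0.011), by -1.94 and -0.80 in the libraries of high and low share. Its call was lost without ZN-c5 2 (adjusted p = 0.0557). Of 28 genes of ribosome biogenesis linked to MYC, 0 rose, 6 fell and 22 did not pass, with 20 down when adjusted over the list alone. NOP16 fell by 0.84 on the log2 scale (SE 0.12) and NOP2 by 0.85 (SE 0.15), both nucleolar proteins. That list fell (mean log2 -0.49, camera adjusted p = 8.33e-11), with differences of -0.45 and -0.48 in the libraries of high and low share.

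**Figure D3:**
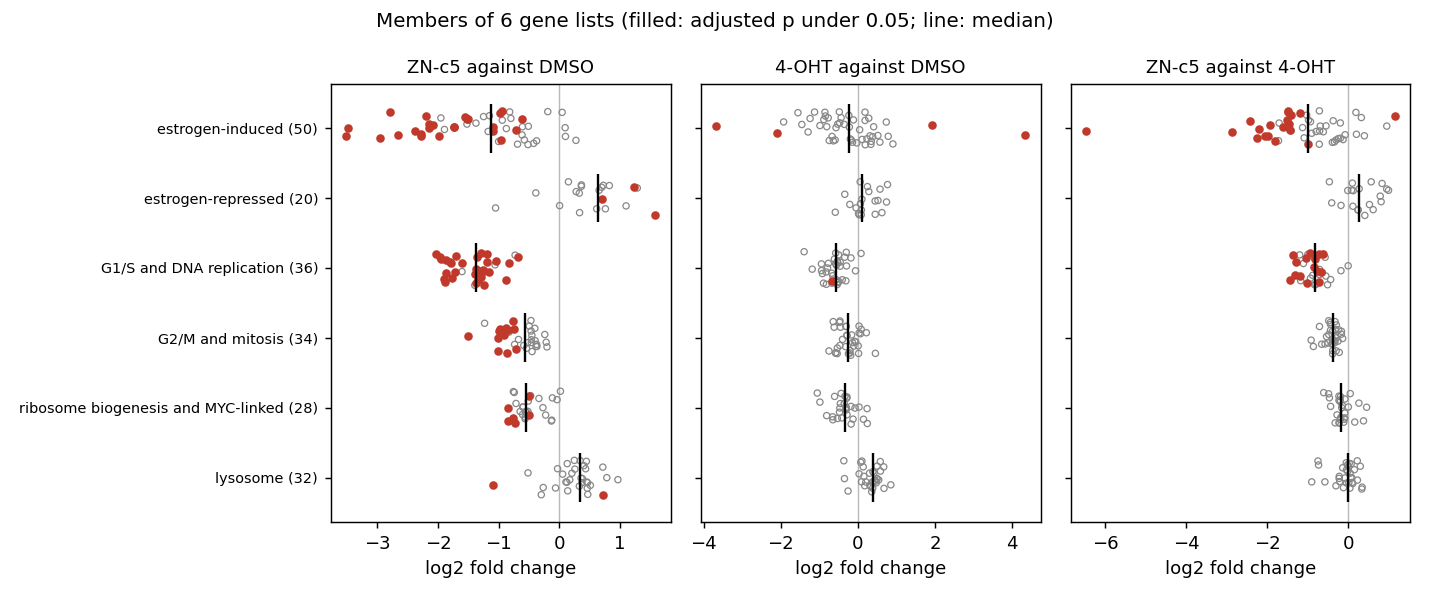
Log2 fold changes (x axis) of the tested members of 6 gene lists in the 3 comparisons, with 1 point per gene, filled where the edgeR adjusted p was under 0.05, and the list median as a line. Of the 36 G1/S and DNA replication genes, 32 are filled with ZN-c5, 1 with 4-OHT and 15 between the compounds.

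A further 6 lists passed, and each of these calls was lost with an estimated correlation. For CDK inhibitors and quiescence the estimated correlation itself (-0.0154) lay below the preset 0.01. By fry, the other alternative, lysosome genes (adjusted p = 0.00629), efflux genes (0.00294), CDK inhibitors (0.00434) and p53 targets (0.0143) passed. Fatty acid synthesis (fry adjusted p = 0.0502) and mitochondrially encoded mRNAs (0.362) did not. Lysosome genes lay higher with ZN-c5 (mean log2 0.25, camera adjusted p = 3.95e-05; adjusted p = 0.121 with an estimated correlation). Only NEU1, a sialidase (log2 0.73, SE 0.12), rose and GLA, alpha-galactosidase A (log2 -1.09, SE 0.17), fell, with 30 of 32 not passing and 11 up and 1 down when adjusted over the list alone. Cholesterol efflux genes driven by LXR lay higher (camera adjusted p = 0.000761; adjusted p = 0.0854 with an estimated correlation), with 2 of 10 raised, LPCAT3 (log2 0.66, SE 0.11) and MYLIP (0.58, SE 0.11), and 5 when adjusted over the list alone. Genes of CDK inhibitors and quiescence lay higher (camera adjusted p = 0.00197; adjusted p = 0.0731 with an estimated correlation), with BTG1, an antiproliferative factor, the 1 member of 15 that rose (log2 0.78, SE 0.17) and 4 raised when adjusted over the list alone. Targets of p53 lay higher (camera adjusted p = 0.00526; adjusted p = 0.162 with an estimated correlation), with TP53INP1 (log2 0.89, SE 0.11) and CCNG1 (0.62, SE 0.13) up and the exonuclease gene AEN (-0.53, SE 0.12) down among 23, and 6 up and 1 down when adjusted over the list alone. Fatty acid synthesis genes lay lower (camera adjusted p = 0.0238; adjusted p = 0.377 with an estimated correlation) with 0 of 20 passing, and 3 down when adjusted over the list alone. This call was lost without DMSO 1 (adjusted p = 0.182) and without ZN-c5 2 (0.0886). The 13 mitochondrially encoded mRNAs lay lower (mean log2 -0.70, camera adjusted p = 0.0199; adjusted p = 0.629 with an estimated correlation) with 0 passing, also when adjusted over the list alone. They differed by -0.72 in the libraries of high share and by 0.25 in those of low share, and the call was lost without DMSO 1 (adjusted p = 0.493), DMSO 3 (0.0743) or ZN-c5 2 (0.199). With a term for the libraries of high mitochondrial share the calls of fatty acid synthesis (mean log2 -0.16, camera adjusted p = 0.0814) and of the mitochondrially encoded mRNAs (-0.23, 0.302) were lost. In the libraries of high and low share, the differences were 0.19 and 0.21 for lysosome genes, 0.38 and 0.37 for efflux genes, 0.25 and 0.72 for CDK inhibitors and quiescence, 0.14 and 0.21 for p53 targets, and -0.17 and -0.16 for fatty acid synthesis.

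The other 11 lists did not pass (camera adjusted p = 0.0542 to 0.97). The BCL2 family passed in 2 of the 9 fits that left out 1 library (lowest camera adjusted p = 0.0259). In these 11 lists, single genes passed. They were FOXA1, a pioneer factor for the estrogen receptor (log2 0.50, SE 0.11), among 20 luminal identity genes, ACAT2, a cholesterol synthesis enzyme (-0.81, SE 0.12), among 26, SLC7A5, an amino acid transporter (-1.09, SE 0.23), among 8 aryl hydrocarbon receptor targets, RET, a receptor tyrosine kinase (-1.09, SE 0.18), and 1 further gene up among 20 growth factor receptor genes, and CD44, a hyaluronan receptor (-1.22, SE 0.19), among 10 basal and mesenchymal markers. Of 25 unfolded protein and amino acid stress genes DDIT4, an inhibitor of mTORC1, rose (log2 0.84, SE 0.12) and 1 fell. Of 15 BCL2 family genes 2 rose, with the proapoptotic BAK1 at log2 0.89 (SE 0.16), and of 24 hypoxia and glycolysis genes 3 rose, with NDRG1 at 0.71 (SE 0.14). None of 19 NRF2 targets and none of 20 interferon-stimulated genes passed with edgeR, although 5 NRF2 targets fell and 1 interferon-stimulated gene rose when adjusted over the list alone. Adjusted over the list alone, the other counts were 2 up among luminal identity genes, 1 down among cholesterol synthesis genes, 2 up and 2 down among stress genes, 1 down among aryl hydrocarbon receptor targets, 3 up and 1 down in the BCL2 family, 2 up and 1 down among growth factor receptor genes, 3 up among hypoxia genes, 1 up and 1 down among basal markers, and 1 up among markers of other cell types. Of 19 markers of other cell types 7 were tested, and VWF, which rose, went from 0.12 to 0.76 CPM. The markers summed to 35.5, 40.5 and 49.7 CPM in DMSO 1, DMSO 3 and ZN-c5 3 and to at most 32.8 CPM in the other 6 libraries. COL1A1, a collagen gene, was the highest with 21.2 CPM in DMSO, 19.1 in ZN-c5 and 13.6 in 4-OHT. RET and SLC7A5 are also members of the list of estrogen-induced genes. The median, mean or direction of the test differed in sign for the luminal, hypoxia, basal and other-cell lists.

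Among genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups, the highest fold changes with ZN-c5 belonged to DTX4, a ubiquitin ligase of the Notch pathway (log2 3.94, SE 0.60), RGCC, a regulator of the cell cycle (2.93, SE 0.26), MME, a membrane metallopeptidase (2.73, SE 0.56), and ZNF30, a zinc finger gene (2.30, SE 0.28). PCDHGB7 (3.78, SE 0.79) shares exons with other protocadherins of its cluster, so its value is uncertain. The lowest of these genes were LINC01016 (-4.02, SE 0.32), RUBCNL, an autophagy gene (-3.82, SE 0.41), SIGLEC15, a sialic acid receptor (-3.67, SE 0.36), STC2 and GREB1. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 20386 genes called 631 genes, 171 higher and 460 lower with ZN-c5, of which 71 and 303 changed at least 2-fold. The DESeq2 test called 1364. Fits scaled by library totals alone and fits of log2(FPKM + 1) split the calls as 208 higher and 353 lower, and 270 higher and 367 lower. A term for the 3 libraries of high mitochondrial share gave 1041 genes and ended the call of PCDHGB7 (log2 3.73, SE 0.91, edgeR adjusted p = 0.077). The 6 libraries of low share, where DMSO 2 is the only control and the other groups give the spread, gave 226, and the 6 libraries of DMSO and ZN-c5 fitted alone gave 312. The count was 318 without DMSO 1, 372 without DMSO 3, 293 without ZN-c5 1, 296 without ZN-c5 2 and 416 without ZN-c5 3. Among the genes named for this comparison, calls were lost without a single library for DTX4 (DMSO 3, adjusted p = 0.0514), CD44 (ZN-c5 2, 0.0557), RET (DMSO 1, 0.0634), GLA (ZN-c5 1, 0.0504) and LPCAT3 (ZN-c5 1, 0.0581). The calls of FOXA1, CCNG1 and AEN were lost in all 9 fits that left out 1 library, those of BTG1, MME, PCDHGB7, SLC7A5, MYLIP and NDRG1 in 7, that of NOP58 in 5, those of NOP2, BAK1 and VWF in 4, those of EFNA1, PSCA and NOP56 in 3 and that of NEU1 in 2.

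The second comparison asked which genes 4-OHT changed against DMSO. KRT13, which encodes keratin 13 (chromosome 17, 41500981 to 41505613), rose from 12.6 ± 0.67 to 255 ± 33.1 CPM (log2 4.34, SE 0.21, edgeR adjusted p = 0.000125, n = 3 libraries each). SERPINA1, which encodes alpha-1 antitrypsin, rose from 10.1 ± 2.14 to 37.9 ± 7.52 CPM (log2 1.91, SE 0.21, edgeR adjusted p = 0.0166). GREB1 fell from 208 ± 32.4 to 16.3 ± 7.0 CPM (log2 -3.68, SE 0.30, edgeR adjusted p = 0.005). Of the 50 estrogen-induced genes 2 rose (KRT13 and SERPINA1), 2 fell (GREB1 and TMPRSS3, a serine protease, at log2 -2.11, SE 0.31) and 46 did not pass, against 7 up and 20 down when adjusted over the list alone. The list lay lower (mean log2 -0.27, camera adjusted p = 0.0153; adjusted p = 0.0845 with an estimated correlation and 0.00346 by fry), and by -0.30 among the libraries of low mitochondrial share. PGR was at log2 -1.29 (SE 0.21, edgeR adjusted p = 0.0778), TFF1 at -0.77 (SE 0.20, adjusted p = 0.175), CCND1 at -0.48 (SE 0.16, adjusted p = 0.234) and MKI67 at -0.64 (SE 0.18, adjusted p = 0.187), none of which passed. PGR passed without 4-OHT 1 (adjusted p = 0.0426). MYC was at log2 -0.03 with a 95% interval of -0.55 to 0.49 (0.58 among the libraries of low share), and ESR1 at -0.29 with an interval of -2.70 to 2.11.

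Genes of G1/S and DNA replication fell as a list with 4-OHT (mean log2 -0.59, camera adjusted p = 2.51e-17; adjusted p = 0.0172 with an estimated correlation). Of the 36 members 0 rose, 1 fell (MCM6, log2 -0.68, SE 0.10, edgeR adjusted p = 0.0482) and 35 did not pass, against 26 down when adjusted over the list alone. Ribosome biogenesis genes fell as a list (mean log2 -0.35, camera adjusted p = 1.59e-06; adjusted p = 0.0124 with an estimated correlation) with 0 of 28 passing, against 5 down when adjusted over the list alone. Lysosome genes lay higher (mean log2 0.31, camera adjusted p = 3.06e-07; adjusted p = 0.0845 with an estimated correlation) with 0 of 32 passing and 5 up when adjusted over the list alone. Among the libraries of low mitochondrial share these 3 lists differed by -0.66, -0.30 and 0.24. A further 7 lists passed with the preset correlation and not with an estimated one, and none of their members passed. By fry, CDK inhibitors and quiescence (adjusted p = 0.0113) and estrogen-repressed genes (0.0253) passed, as did the lysosome genes above (0.00346). G2/M (fry adjusted p = 0.0983), mitochondrially encoded mRNAs (0.209), the BCL2 family (0.177), aryl hydrocarbon receptor targets (0.104) and hypoxia (0.13) did not. G2/M genes lay lower (camera adjusted p = 0.000588; adjusted p = 0.422 with an estimated correlation), with 2 down when adjusted over the list alone. The mitochondrially encoded mRNAs lay lower (mean log2 -0.95, camera adjusted p = 0.000741; adjusted p = 0.458 with an estimated correlation), but 0.19 higher among the libraries of low share, with 0 passing when adjusted over the list alone. Genes of CDK inhibitors and quiescence lay higher (camera adjusted p = 0.0153; adjusted p = 0.0962 with an estimated correlation), with 2 up when adjusted over the list alone. This call was lost without DMSO 2 (adjusted p = 0.232). Estrogen-repressed genes lay higher (camera adjusted p = 0.0199; adjusted p = 0.162 with an estimated correlation), with 3 up when adjusted over the list alone, a call lost without DMSO 2 (0.0937) or 4-OHT 3 (0.0652). BCL2 family genes lay higher (camera adjusted p = 0.0199; adjusted p = 0.437 with an estimated correlation), with 0 passing when adjusted over the list alone, a call lost without DMSO 3 (0.067) or 4-OHT 3 (0.0526). Aryl hydrocarbon receptor targets lay lower (camera adjusted p = 0.0377; adjusted p = 0.329 with an estimated correlation), with 3 down when adjusted over the list alone, and the call was lost without DMSO 1 (0.101), DMSO 3 (0.067), 4-OHT 1 (0.0516) or 4-OHT 3 (0.115). Hypoxia and glycolysis genes lay higher (camera adjusted p = 0.0473; adjusted p = 0.432 with an estimated correlation), with 0 passing when adjusted over the list alone, a call lost without DMSO 1 (0.0995), DMSO 3 (0.122), ZN-c5 1 (0.0519), ZN-c5 2 (0.0515), 4-OHT 2 (0.0802) or 4-OHT 3 (0.169). In the libraries of low share these lists differed by -0.23 for G2/M, 0.60 for CDK inhibitors and quiescence, 0.17 for estrogen-repressed genes, -0.04 for the BCL2 family, -0.06 for aryl hydrocarbon receptor targets and -0.03 for hypoxia. As means of edgeR log2 fold changes in a fit of those 6 libraries, the BCL2 family was at 0.507 (0.233 in all 9). Aryl hydrocarbon receptor targets were at -0.515 (-0.505) and hypoxia at 0.059 (0.054). The 2 measures thus differ for these lists, and both rest on DMSO 2 as the only control. With a term for the libraries of high mitochondrial share the calls of the mitochondrially encoded mRNAs (mean log2 -0.16, camera adjusted p = 0.566), BCL2 family (-0.01, 0.574), aryl hydrocarbon receptor targets (0.03, 0.377) and hypoxia (0.00, 0.51) were lost. The other 11 lists did not pass (camera adjusted p = 0.0557 to 0.897), and none of their members passed with edgeR. Interferon-stimulated genes (lowest camera adjusted p = 0.0125) and fatty acid synthesis genes (0.0393) each passed in 2 of the 9 fits that left out 1 library. Cholesterol synthesis genes passed in 1 (0.0372). Adjusted over the list alone, 3 LXR targets and 1 stress gene rose, 1 fatty acid synthesis gene fell, and 1 growth factor receptor gene rose and 2 fell. No member passed so adjusted in the luminal identity, p53, cholesterol synthesis, NRF2, interferon, basal and other-cell lists. The median, mean or direction of the test differed in sign for the luminal, stress, NRF2 and other-cell lists.

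With 4-OHT, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 31 genes, 16 higher and 15 lower, of which 14 and 11 changed at least 2-fold. After KRT13, and among genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups, the highest were LINC01588 (log2 3.19, SE 0.29), TGM2, transglutaminase 2 (2.62, SE 0.30), ZNF30 (2.34, SE 0.28) and CD22, a sialic acid receptor known from B cells (2.30, SE 0.25). The lowest of these genes after GREB1 were SIGLEC15 (-2.58, SE 0.34), DIXDC1, a Wnt pathway gene (-2.54, SE 0.27), CALML4, a calmodulin-like gene (-2.41, SE 0.32), and TMPRSS3. At an unadjusted p under 0.05, 3031 genes passed, and the DESeq2 test called 615 after adjustment. A term for the libraries of high mitochondrial share gave 16 genes. The 6 libraries of low share, with DMSO 2 as the only control, gave 82, and the 6 libraries of DMSO and 4-OHT fitted alone 17. That term ended the calls of SERPINA1 (log2 1.80, SE 0.24, edgeR adjusted p = 0.0651), TGM2 (2.31, SE 0.37, 0.1), CD22 (2.12, SE 0.29, 0.0659) and SIGLEC15 (-2.22, SE 0.33, 0.0866). It also ended those of DIXDC1 (-2.36, SE 0.30, edgeR adjusted p = 0.0562), CALML4 (-2.16, SE 0.35, 0.102) and TMPRSS3 (-2.0, SE 0.34, 0.109). The count was 11 without DMSO 1, 17 without DMSO 2, 13 without DMSO 3, 18 without ZN-c5 1, 11 without ZN-c5 2, 7 without 4-OHT 2 and 8 without 4-OHT 3. KRT13, LINC01588 and GREB1 passed in all 9 fits that left out 1 library, and KRT13 differed by 4.26 and GREB1 by -3.49 among the libraries of low share. SERPINA1 was lost without DMSO 1 (adjusted p = 0.0517), 4-OHT 2 (0.0515) and 4-OHT 3 (0.0635), CD22 without DMSO 1 (0.0517) and 4-OHT 3 (0.0635), and DIXDC1 without DMSO 1 (0.0561), DMSO 3 (0.0532) and 4-OHT 2 (0.0872). TGM2 was lost in 6 of these fits, ZNF30, SIGLEC15 and CALML4 in 7, TMPRSS3 in 8 and MCM6 in all 9.

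The third comparison set the compounds against each other at the same dose and time. KRT13 was lower with ZN-c5 than with 4-OHT by log2 -6.48 (SE 0.23, edgeR adjusted p = 9.01e-06), since ZN-c5 lowered it from 12.6 ± 0.67 to 2.86 ± 0.75 CPM (log2 -2.14, adjusted p = 0.000813) where 4-OHT raised it. STC2 was lower with ZN-c5, at 57.8 ± 3.02 against 425 ± 73 CPM (log2 -2.88, SE 0.14, edgeR adjusted p = 8.92e-05). PGR was lower with ZN-c5, at 4.09 ± 0.30 against 11.6 ± 3.40 CPM (log2 -1.50, SE 0.21, edgeR adjusted p = 0.0142). GREB1 did not pass (log2 0.19, 95% interval -0.43 to 0.81), nor did TFF1 (-0.19, interval -0.64 to 0.26), CCND1 (-0.12, interval -0.48 to 0.24) or ESR1 (0.24, interval -2.16 to 2.64). Of the 50 estrogen-induced genes 1 was higher with ZN-c5, 19 were lower and 30 did not pass, against 2 higher and 33 lower when adjusted over the list alone. TPD52L1 (log2 -2.05, SE 0.11) and CXCL12 (-2.27, SE 0.17) were among the 19. SLC22A5, a carnitine transporter named after its values were seen, was the 1 higher gene (1.16). The list was lower with ZN-c5 (mean log2 -1.06, camera adjusted p = 7.18e-26), and by -1.07 among the libraries of low mitochondrial share.

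Genes of G1/S and DNA replication were lower with ZN-c5 than with 4-OHT (mean log2 -0.83, camera adjusted p = 2.02e-31). Of 36 members 0 were higher, 15 were lower and 21 did not pass, against 32 lower when adjusted over the list alone. Examples were E2F1 (log2 -1.18, SE 0.15), the helicase cofactor gene CDC45 (-1.30, SE 0.16), the exonuclease gene EXO1 (-1.31, SE 0.17) and RRM2, a subunit of ribonucleotide reductase (-1.43, SE 0.20). MYC was lower with ZN-c5 (log2 -1.48, SE 0.24, edgeR adjusted p = 0.0249), and MKI67 did not pass (log2 -0.86, SE 0.18, edgeR adjusted p = 0.0731). G2/M genes lay lower (camera adjusted p = 8.33e-11; adjusted p = 0.143 with an estimated correlation) with 0 of 34 passing and 9 lower when adjusted over the list alone. Cholesterol synthesis genes lay lower (camera adjusted p = 0.00197; adjusted p = 0.0845 with an estimated correlation), with ACAT2 (log2 -0.66, SE 0.12) the 1 of 26 that passed, and also the 1 when adjusted over the list alone. Interferon-stimulated genes lay higher (camera adjusted p = 0.00194; adjusted p = 0.432 with an estimated correlation) with 0 of 20 passing, also when adjusted over the list alone, a call lost without 4-OHT 3 (adjusted p = 0.0595). Estrogen-repressed genes lay higher (camera adjusted p = 0.00248; adjusted p = 0.0901 with an estimated correlation) with 0 of 20 passing and 5 higher when adjusted over the list alone, a call lost without 4-OHT 1 (0.0516). Ribosome biogenesis genes lay lower (camera adjusted p = 0.0134; adjusted p = 0.0854 with an estimated correlation) with 0 of 28 passing and 2 lower when adjusted over the list alone, a call lost without ZN-c5 1 (0.0656) or 4-OHT 1 (0.0524). LXR targets lay higher (camera adjusted p = 0.0199; adjusted p = 0.174 with an estimated correlation) with 0 of 10 passing and 1 higher when adjusted over the list alone, a call lost without ZN-c5 2 (0.0857) or 4-OHT 2 (0.0885). NRF2 targets lay lower (camera adjusted p = 0.036; adjusted p = 0.137 with an estimated correlation), with the aldo-keto reductase gene AKR1C3 (log2 -0.96, SE 0.14) the 1 of 19 that passed and 1 higher and 3 lower when adjusted over the list alone, a call lost without ZN-c5 1 (0.0658), ZN-c5 2 (0.0922) or 4-OHT 3 (0.148) and without genes far off in 1 library of a group (0.0658). By fry, interferon-stimulated genes did not pass (adjusted p = 0.193). The G2/M, cholesterol synthesis, estrogen-repressed, ribosome biogenesis, LXR and NRF2 lists passed by fry (adjusted p = 0.00913 to 0.0235). Among the libraries of low share the lists passing by camera differed by -0.77 for G1/S, -0.30 for G2/M, -0.26 for cholesterol synthesis, 0.46 for interferon, 0.36 for estrogen-repressed genes, -0.17 for ribosome biogenesis, 0.30 for LXR and -0.24 for NRF2. The other 13 lists did not pass (camera adjusted p = 0.0829 to 0.995). Targets of p53 passed in 2 of the 9 fits that left out 1 library (lowest camera adjusted p = 0.0138), and mitochondrially encoded mRNAs in 1 (0.0417). In these 13 lists TP53INP1 was higher with ZN-c5 (log2 0.60, SE 0.11), RET (-1.61, SE 0.19) and CD44 (-1.57, SE 0.19) were lower, and no other member passed. Adjusted over the list alone, the counts in those 13 lists were 1 lower for luminal identity, 1 higher for p53, 1 lower for lysosome, 3 higher for aryl hydrocarbon receptor targets, 1 higher and 1 lower for the BCL2 family, 5 higher and 2 lower for growth factor receptor genes, 2 lower for hypoxia, 1 lower for basal markers, 1 higher for other cell types, and none for CDK inhibitors, fatty acid synthesis, stress and mitochondrially encoded genes. The median, mean or direction of the test differed in sign for the luminal, fatty acid, BCL2 and basal lists.

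Between the compounds, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 196 genes, 41 higher and 155 lower with ZN-c5, of which 23 and 120 differed at least 2-fold. Again among genes with an average log2 CPM of at least 1 and no overlap between the libraries of the groups, the highest were MME (log2 3.28, SE 0.58), the axon guidance gene SLIT1 (2.67, SE 0.50), SNTB1, a syntrophin gene (2.30, SE 0.32), KRT81, a hair keratin gene (1.81, SE 0.13), and RGCC (1.77, SE 0.25). KRT81 was at 173 ± 10.2 CPM with ZN-c5, 49.3 ± 1.94 with 4-OHT and 41.6 ± 6.32 with DMSO, and as a member of a keratin family with close copies it is uncertain. The lowest of these genes were KRT13, LINC01588 (-4.88, SE 0.32), LINC01016 (-4.73, SE 0.33), PLAC1, a placental gene (-4.56, SE 0.67), and RUBCNL (-3.89, SE 0.41). The DESeq2 test called 653 genes and a term for the libraries of high mitochondrial share gave 326. That term ended the calls of MME (log2 2.94, SE 0.54, edgeR adjusted p = 0.0536) and SLIT1 (2.29, SE 0.44, 0.0557). The count was 88 without ZN-c5 1, 91 without ZN-c5 2, 96 without ZN-c5 3, 88 without 4-OHT 2 and 92 without 4-OHT 3. Calls of named genes were lost for EXO1 without ZN-c5 2 (adjusted p = 0.058), for PGR without ZN-c5 1 (0.0782), ZN-c5 2 (0.0578), ZN-c5 3 (0.0696) or 4-OHT 2 (0.0531), and for RRM2 without ZN-c5 1 (0.0538), ZN-c5 2 (0.06) or ZN-c5 3 (0.0646). Those of RGCC, SNTB1 and PLAC1 were lost in 3 of the 9 fits, that of AKR1C3 in 4, those of MYC and MME in 6, those of ACAT2 and TP53INP1 in 8 and that of SLIT1 in all 9.

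The responses to the compounds were also set side by side, with the same 3 DMSO libraries behind both. Of the 460 genes lowered by ZN-c5, 407 had a negative log2 fold change with 4-OHT (medians -1.21 with ZN-c5 and -0.47 with 4-OHT), and 116 of the 460 also differed between the compounds. Of the 171 raised by ZN-c5, 155 had a positive value with 4-OHT (medians 0.91 and 0.45), and 28 also differed. These shares of the same sign, 88.5% and 90.6%, stood against 65.2% (62.5% to 70.3%) and 72.8% (66.8% to 76.7%) in 20 simulations where ZN-c5 acted as measured and 4-OHT had no effect. In these simulations the shared DMSO libraries alone tie the signs together. The medians with 4-OHT were then -0.12 and 0.21. All simulations here drew each gene on its own and left out the difference of DMSO 1, DMSO 3 and ZN-c5 3 from the other libraries. No 4-OHT library had a high mitochondrial share, so this difference can also tie the signs. The excess over the simulated shares therefore cannot be assigned to 4-OHT. Genes that passed with both compounds and in the same direction were 12 lowered genes, GREB1, SIGLEC15, DIXDC1 and MCM6 among them, and 4 raised genes, ZNF30 and, named after their values were seen, FECH, DUSP3 and ACSS1. The count of 16 shared genes became 7, 8 and 8 without DMSO 1 to 3, 6, 3 and 10 without ZN-c5 1 to 3, and 8, 1 and 3 without 4-OHT 1 to 3. It became 8 with a term for the libraries of high mitochondrial share. In the 6 libraries of low share it was 65, but there DMSO 2 alone stood behind both compounds, so its own deviation enters both and the 65 cannot be read as a shared response. In opposite directions, 5 genes passed. Independent lists of these sizes would share 0.338 lowered, 0.134 raised and 0.487 opposite genes. Simulated unchanged groups gave 0 genes in every class, which leaves no number to compare with. Part of the overlap may come from the shared controls, which are too few to be split. Across genes with an average log2 CPM of at least 1, the covariance of the fold changes was 0.130 against 0.0748 simulated, a difference of 0.0552, and the correlation was 0.463 against 0.498. A line through the origin with equal errors gave a slope of ZN-c5 on 4-OHT fold changes of 2.37 over 570 genes called with either compound, 511 of which had the same sign (89.6%, against 67.8% in the simulations without an effect of 4-OHT). The slope depended on how genes were chosen: it was 2.46 over the 562 genes called with ZN-c5 and 1.76 over 374 genes called for the mean of both compounds, a choice that favours neither. In 20 simulations where both compounds acted alike, it was 1 (0.92 to 1.05) over genes called with either compound. Over genes called with ZN-c5 it was 1.13 (1.06 to 1.19) there. Over the 50 estrogen-induced genes, which were fixed without regard to calls, the slope was 2.25, with a correlation of 0.353 and 31 of the same sign. No simulation gave the share of the same sign for this list without an effect of 4-OHT. With so loose a relation, the slope cannot show that ZN-c5 moved the same genes further. Genes are not replicates, and these slopes carry no p-value.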

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

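The differences between the compounds below were computed after the calls in opposite directions were seen, and the tests of what lies behind these 5 genes were chosen only after that result was seen. Genes were singled out because 4-OHT raised them and ZN-c5 lowered them against the same DMSO libraries, each past the threshold, with a difference between the compounds that passed as well. KRT13 (keratin 13) had a difference of log2 -6.48 for ZN-c5 minus 4-OHT (SE 0.23). LINC01588 had -4.88 (SE 0.32), UGT2B15, a glucuronosyltransferase that acts on steroids, -3.79 (SE 0.30), and CD22 -3.66 (SE 0.26). FCGR2B, an Fc receptor gene, had 31 reads over the DMSO libraries, 0 over the ZN-c5 libraries and 461 over the 4-OHT libraries. With 3 reads set as the floor over the group, 4-OHT lay at least 160-fold above ZN-c5 (log2 7.32) and DMSO at least 11.4-fold above it. UGT2B15 and FCGR2B have close paralogs, and their reads may belong in part to those, which no table here tests.

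Simulated unchanged groups against the shared DMSO libraries gave at most 0 genes called in opposite directions, but they gave 0 in every direction, so this says nothing about chance in those controls. With the term for the 3 libraries of high mitochondrial share, 5 of the 5 genes kept the direction of each response and passed between the compounds, which argues against those libraries as the whole cause. In that fit the rise with 4-OHT passed with edgeR for KRT13 (adjusted p = 0.00391) and LINC01588 (0.0432). It did not pass for CD22 (adjusted p = 0.0659, log2 2.12 against 2.30 without the term), UGT2B15 (0.137, log2 1.86 against 1.96) and FCGR2B (0.172, fitted log2 3.65 against 3.79), whose values moved little. An action of 4-OHT like that of estrogen on estrogen-induced genes may lie behind the pattern and stays open. Of the 5 genes 1, KRT13, was in the list of 50 estrogen-induced genes (Fisher exact p = 0.0122), and 1 gene is too few to decide. Of the 16 genes raised by 4-OHT, KRT13 and SERPINA1 were in that list, against 0.0392 expected. Of the 15 genes lowered by 4-OHT, GREB1 and TMPRSS3 were in it as well, and the list as a whole lay lower with 4-OHT (mean log2 -0.27).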

How the results depend on the processing

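The alternatives with a term for, or without, the libraries of high mitochondrial share, without mitochondrial genes, without genes far off in 1 library and over genes called for the mean of both compounds were chosen after seeing the data, as were the splits of the libraries, and the others were planned. With 3 libraries per group the number of calls depended on single libraries, and the cause was not tested. Genes with a small change or few reads stay open with 3 libraries per group. In simulated data edgeR called 12 of 100 2-fold changes. Few genes were changed there, which makes the adjusted threshold stricter than in a comparison with 631 calls. Gene counts are given below in the order ZN-c5 against DMSO, 4-OHT against DMSO and ZN-c5 against 4-OHT, where 631, 31 and 196 were called.

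The DESeq2 test gave 1364, 615 and 653 genes. Library totals gave 561, 20 and 159, log2(FPKM + 0.1) gave 11 for 4-OHT against DMSO, and log2(FPKM + 1) without a filter 108 between the compounds. The 6 libraries compared alone gave 312, 17 and 195. The term for the mitochondrial share gave 1041, 16 and 326, with 8 shared responses in place of 16, and the 6 libraries of low share 226, 82 and 136, with 65 shared. In these 6 libraries DMSO 2 was the only control, so that the 226, 82 and 65 rest on 1 library. In those 6 libraries the list of mitochondrially encoded mRNAs turned to 0.307 with ZN-c5 and 0.243 with 4-OHT (means of edgeR log2 fold changes), against -0.70 and -0.95 in all 9. Without genes far off in 1 library the counts were 780, 45 and 284, of which 630, 31 and 196 were also called with all genes. A block for the replicate number gave 480, 4 and 121 genes and 1 shared response. Whether the numbers pair the libraries stays open. Only 2 of 9 same-number pairs had a correlation over 0.1 (highest 0.148), but 5 of the 9 libraries correlated best with a library of their own number. The labels do not say that equal numbers mark a shared culture, so the block is given as an alternative only.

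Leaving out 1 library gave 293 to 650, 7 to 25 and 88 to 253 genes, 1 to 10 shared responses and slopes of 2.21 to 2.49 (2.37 with all). Over genes called for the mean of both compounds the slope was 1.76. In place of 11, 11 and 9 lists, it gave 9 to 12, 7 to 12 and 7 to 10. An estimated correlation gave 4, 2 and 2 lists, and fry 10, 6 and 8. Over the fits without 1 library 527 of 747 calls of named genes passed and none reversed. Of the 83 such calls with all libraries, 20 were lost with the replicate block and 10 with the term for the mitochondrial share, and 0 reversed. In the 6 libraries of low share 0 reversed as well, but calls were lost, those of GREB1, CDK1 and MYC with ZN-c5 among them. These losses are not counted here, since DMSO 2 was the only control. With ZN-c5, log2 fold changes there were -3.351 for GREB1 against -3.483 in all 9, and -0.851 for CDK1 against -0.858. MYC shrank to -0.784 from -1.507. Of the 31 list calls, 6 were lost with that term (fatty acid synthesis and mitochondrially encoded mRNAs with ZN-c5, and the latter, BCL2, aryl hydrocarbon receptor and hypoxia with 4-OHT), 4 with log2(FPKM + 1) and 1, NRF2 targets between the compounds, without genes far off in 1 library, and in the 6 libraries of low share 4 were lost and 2 reversed.

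The 6 libraries of a comparison make 10 splits, too few for a share under 0.05. For ZN-c5 against DMSO, 2 splits gave at least 631 genes, the real one and that of DMSO 1, DMSO 3 and ZN-c5 3 from the others. The latter follows the mitochondrial share, gave 1027 genes, the highest of the other splits, and points to a structure of the samples. With the term for that share 1041 genes differed between ZN-c5 and DMSO. In the other comparisons 1 split, the real one, gave as many genes (31 and 196, highest other 5 and 5), and 1 split gave as many lists in each comparison (11, 11 and 9, highest other 9, 5 and 5).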

Other observations

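The tests of pathways and explanations in this part were chosen only after the result was seen, apart from the test of a true loss of ESR1, whose bounds were written before its result was seen. Of 307 KEGG pathways, 4 lay higher and 9 lower with ZN-c5 than with DMSO by camera, and 0 passed with an estimated correlation, while fry called 36. Among the 9 were pathways of DNA replication and repair, named here after their values were seen, with adjusted p of 0.204 to 0.321 with an estimated correlation. Of the 36 tested genes of DNA replication 18 fell (camera adjusted p = 2.68e-16), of 54 in the Fanconi anemia pathway, which repairs crosslinks between strands, 15 fell (1.22e-08), of 42 in homologous recombination 11 fell (5.34e-07), and of 23 in mismatch repair 9 fell (2.63e-06). Base excision repair had 8 of 33 genes down (0.00325). Many genes are shared between these pathways. By fry their adjusted p was 0.000639 to 0.00145.

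Between the compounds 11 of the 307 pathways lay lower with ZN-c5 and 0 higher, and with 4-OHT against DMSO 19 lay higher and 2 lower, of which 0 passed with an estimated correlation. Between the compounds, 7 of 36 DNA replication genes and 9 of 120 cell cycle genes were lower with ZN-c5 (camera adjusted p = 3.4e-13 and 4.34e-06; adjusted p = 0.312 and 0.204 with an estimated correlation). With 4-OHT the pathway of porphyrin metabolism, which makes heme, lay higher with 2 of 25 genes up (camera adjusted p = 0.0132; adjusted p = 0.474 with an estimated correlation). The Ribosome pathway lay higher with 4-OHT (camera adjusted p = 4.2e-07; adjusted p = 0.772 with an estimated correlation) with 0 of 130 genes passing with edgeR. The share of reads on ribosomal-protein genes was 7.95% in DMSO and 10.5% in 4-OHT, and DMSO 2, the DMSO library of low mitochondrial share, had 11.2%.

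DMSO 1, DMSO 3 and ZN-c5 3 differed from the other libraries of their own groups beyond their mitochondrial reads. In a fit with a mean per group, 426 genes were higher and 1052 lower. The libraries compared with them were thus DMSO 2, ZN-c5 1 and ZN-c5 2. The group without a library of high share added nothing to this difference, and DMSO 2 alone stood for DMSO. The same difference was used for length and GC below. The totals of DMSO 1, DMSO 3 and ZN-c5 3 cannot decide on a shortage of reads. The lowest of these was 69.2 M reads in DMSO 3 against 65 M in DMSO 2, but mitochondrial reads made up 23.4% and 12.2% of these 2 totals. A bias by gene length was there, with length taken as the ratio of counts to FPKM in these data. It was tested on 9571 protein-coding genes outside the mitochondrial chromosome with an average log2 CPM of at least 3. The median log2 difference went from -0.42 in the group of shortest genes to 0.23 in the group of longest genes (10 groups of equal size), a span of 0.65. Medians also fell with GC content, from 0.09 in the group of lowest to -0.17 in that of highest GC. This span of -0.27 lay between the bounds set for that test. Fitted together across genes, length carried a log2 change of 0.18 per SD and GC -0.045, which argues against GC as the larger of the 2. Both accounted for a share of 0.157 of the variance between genes, so most of the difference stays unexplained. A difference in RNA handling or library preparation is a candidate explanation for the length trend, and a biological difference between these cultures was not tested.

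ESR1 was 1 of 414 genes, of 10169 with an average log2 CPM of at least 3, that 1 library of a group counted at least 4-fold apart from both others. The 3 libraries of high mitochondrial share held 28.7% of these events. The 4-OHT libraries, where no share was high, held 62, 69 and 62 events, which argues against that share as the cause there. ZN-c5 3 held 56 against 58 and 68 in ZN-c5 1 and ZN-c5 2. In DMSO, a gene shifted by the share would be counted as an event of DMSO 2, which held 91, so there the test cannot decide. A true loss of ESR1 stays open: the 50 estrogen-induced genes lay -0.07 on average from the other libraries of the group (DMSO 1 -0.12, ZN-c5 2 -0.02, 4-OHT 3 -0.06), above the bound written before, but ZN-c5 had already lowered this list and 4-OHT acts on the same receptor, which leaves DMSO 1 alone. Summing counts over genes that overlap on the same strand ended 20.5% of the cases, and 231 of the 414 genes have no such overlap, so reads moved between gene models stay open as a cause of part of them. A candidate explanation is the upstream estimation of counts from transcripts, which could not be tested without reads.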
